A study of Treponema denticola ATCC 35405 with 6 samples.

How the data were processed

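Total RNA from 6 cultures of Treponema denticola ATCC 35405 was measured by RNA sequencing. Per the labels' protocols, cells were pelleted under anaerobic conditions and lysed by bead beating, RNA was purified on columns, and libraries were made with a directional kit and PCR. The labels name no molecular identifiers and no depletion of ribosomal RNA. The authors deposited raw counts of reads per gene, as a table of the whole series and as 1 table per library. The values are whole numbers with totals that differ between libraries. The submitters' processing notes name FastQC 0.11.7, MultiQC 1.1, Trimmomatic 0.39 and DESeq2 1.32.0, with no role or order. The aligner, the counting tool, its strand setting and the genome build are not given in the sources used here. Reads shared between near-identical or overlapping genes could therefore not be examined. The library tables held the same counts as the series table, which was used.

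Libraries were assigned to control and CBD by their titles, and table columns to libraries by the descriptions in the labels. The series' design text speaks of 3 control and 3 test cultures, so the replicates are separate cultures. Groups of 3 were compared in 1 contrast, CBD over control, fitted without further terms. Rows of the table were kept as deposited, and each names a gene. Genes with too few counts were removed with edgeR's filterByExpr, which left 2506 of 2613 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM values are counts scaled to the TMM-adjusted library size (edgeR cpm). Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Log2 CPM for correlations and principal components used a prior count of 2. TMM factors ranged from 0.86 to 1.39, with 1.14 ± 0.255 (SD, n = 3) in controls and 0.893 ± 0.0434 (SD, n = 3) with CBD.

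Depth was between 8868946 and 10787858 counts per library, and the median gene had between 284 and 477 counts. Counting error is thus small for most genes, and the spread between cultures sets the precision. Counts come from PCR-amplified reads, so counting error would understate the error of rare transcripts. The test was run on simulated data for this comparison, with counts drawn for the 2506 genes from the control means, library sizes and fitted dispersions and 200 genes changed. Over 5 simulations it recovered 44.6% of genes changed 2-fold and 95.2% of those changed 4-fold, and 4.26% of its calls were false. Genes were drawn independently and with the same dispersion in both groups. The joint movement of genes and the larger spread of the controls were thus left out, and the rates may differ in the data. The counter of runs returned a planted run of 10 called genes, as it must if the code is right. The test of neighbour correlation called 0 of 20 orders of random values. Both check the code and not the power of the search.

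The rule for named genes was fixed before the data were examined. It asked for an adjusted p under 0.05, a mean of at least 20 CPM and no overlap between groups, and ranked by fold change. The parts of the rule and the gene lists that rest on gene names and products could not be applied, because the files pair no identifier with a name and no annotation was used here. For the same reason the tests of gene lists and the removal of ribosomal and transfer RNA genes were not run. The 2 largest rises and the 2 largest falls are named, which is fewer each way than the rule set, and other genes are summarised.

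Runs were defined after the data were seen, as called genes of the same direction that follow each other in the table with identifier numbers rising by 5. RefSeq identifiers of this form are generally numbered along the genome, and the position and strand of the genes were not examined. Significance was tested by 9999 shuffles of the genes over the identifiers. The position of Control 1 was also computed after the data were seen, for genes with a mean of at least 20 CPM, and its intervals come from 2000 bootstrap draws over genes. Those intervals cover the spread between genes and not between cultures. They treat genes as independent, and are too narrow where neighbouring genes move together.

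Alternatives fixed before the data were examined were RLE, upper-quartile and library-size scaling, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), no filter, a filter of 50 counts in every library of a group, the replicate number as a block, each library left out in turn, the library tables, a threshold of 0.01 and glmTreat against 1.5-fold. Removal of the 3 most abundant genes was added after the data were seen.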

Results

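RNA was sequenced from cultures of Treponema denticola ATCC 35405, an anaerobic oral spirochaete found in periodontal disease. Cultures labelled control were compared with cultures treated with CBD, to ask how the transcriptome responded to that compound. The labels give only the abbreviation CBD, which commonly stands for cannabidiol, a cannabinoid of the cannabis plant, and a dose of 5 µg/ml. They do not say whether the controls received the solvent of the compound. Descriptions of the control libraries carry the code MET, whose meaning is not given. Differences are therefore reported between the groups as labelled and are not assigned to the compound alone. There were 3 control and 3 CBD cultures, harvested in log phase, with 1 library each. Between 8868946 and 10787858 reads were assigned to genes per library, with 9590932 ± 1043902 (SD, n = 3) in the controls and 10063891 ± 585733 (SD, n = 3) with CBD. Of 2613 genes listed, between 2593 and 2601 had at least 1 count in each library. The files give locus identifiers without gene names or products, so genes are reported here by identifier and their functions are not described.

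The control cultures varied more than the CBD cultures over all genes. The biological coefficient of variation was 20.9% among the CBD libraries and 32.4% among the controls. The mean Spearman correlation over genes was 0.984 between CBD libraries, with a range of 0.976 to 0.995, and 0.968 between control libraries, with a range of 0.941 to 0.984. Control 1 was the nearest of the controls to the treated cultures. Its mean correlation with the CBD libraries was 0.968, compared with 0.941 for Control 2 and 0.899 for Control 3. The first principal component held 72.1% of the variance, and on it Control 3 lay at -38.1, Control 2 at -21.5, Control 1 at -0.26 and the CBD libraries between 18.3 and 22.1. On the second, with 17.4% of the variance, the scores fell with the replicate number in both groups. Control 1 lay at 16.8, Control 2 at 3.45 and Control 3 at -7.50. CBD 1 lay at 10.8, apart from CBD 2 at -10.1 and CBD 3 at -13.5. Counts were compared between libraries to look for duplicate deposits of a library, and none was found; the closest pair, CBD 2 and CBD 3, differed with a chi-square of 24.4 per degree of freedom.

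**Figure D1:**
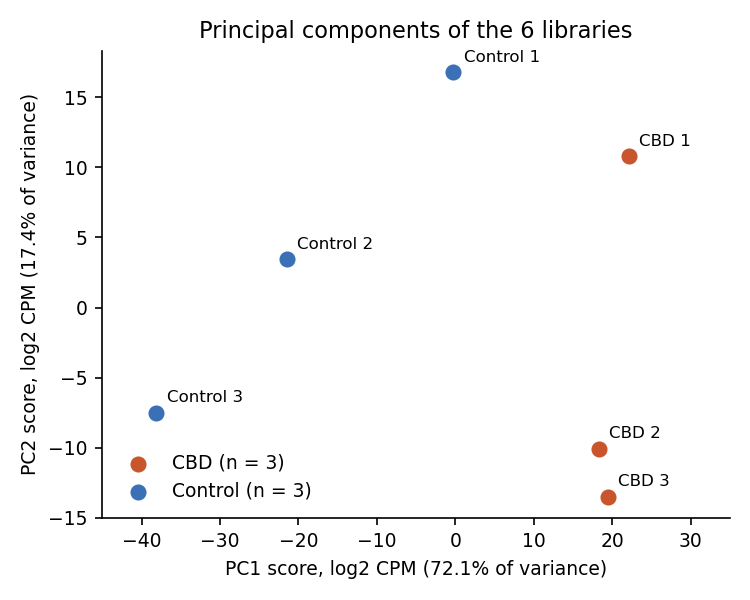
Scores of the 6 libraries on the first (x axis) and second (y axis) principal components of log2 CPM; each point is 1 library, blue for control and orange for CBD. The CBD libraries lie between 18.3 and 22.1 on the first component, and the controls are spread from -38.1 to -0.26; on the second, CBD 1 at 10.8 stands apart from CBD 2 and CBD 3.

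Between CBD and control cultures, 464 of the 2506 genes tested differed, or 18.5%. With CBD, 211 genes rose and 253 fell. The rises were larger: their median was 2.29-fold and the largest was 20.6-fold, while the falls had a median of 1.96-fold and a largest value of 7.27-fold. At least 2-fold changes numbered 148 rises and 117 falls, and at least 4-fold changes 43 rises and 4 falls. At least 8-fold changes were found among the rises alone in the main test, in 20 genes. The largest fall, that of TDE_RS09180, was beyond 8-fold with library size as the only scaling and without CBD 1, with log2 fold changes of -3.25 and -3.23. Calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and 944 genes had an unadjusted p under that level. All 464 called genes had control and CBD values that did not overlap. Of all tested genes 42.3% did so, where chance gives 10% on average for 3 against 3. Genes moved together, so this share can vary widely by chance and the comparison is no test.

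The number of calls depended on single libraries, on the threshold, on the tool and on a replicate block, and the balance of rises and falls on the scaling. The count was 1045 genes without Control 1, 46 without Control 2, 50 without CBD 2 and 53 without CBD 3. It was 310 without Control 3, when the falls went from 253 to 145. With library size alone as the scaling, the median gene shifted by -0.36 on the log2 scale and the calls became 139 rises and 424 falls, so that 24.7% of calls were rises compared with 45.5% in the main test. At least 2-fold changes, with 148 rises and 117 falls in the main test, were then 120 rises and 375 falls, and with upper-quartile factors 131 rises and 171 falls. The DESeq2 Wald test called 704 genes, and edgeR called 45 at an adjusted p under 0.01 and 49 with glmTreat against 1.5-fold. With the replicate number as a block edgeR called 816 genes. No called gene changed sign under any setting tried. Called genes had groups that did not overlap, so leaving out a library could hardly change a sign. The kept signs are therefore no test of the calls.

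**Figure D2:**
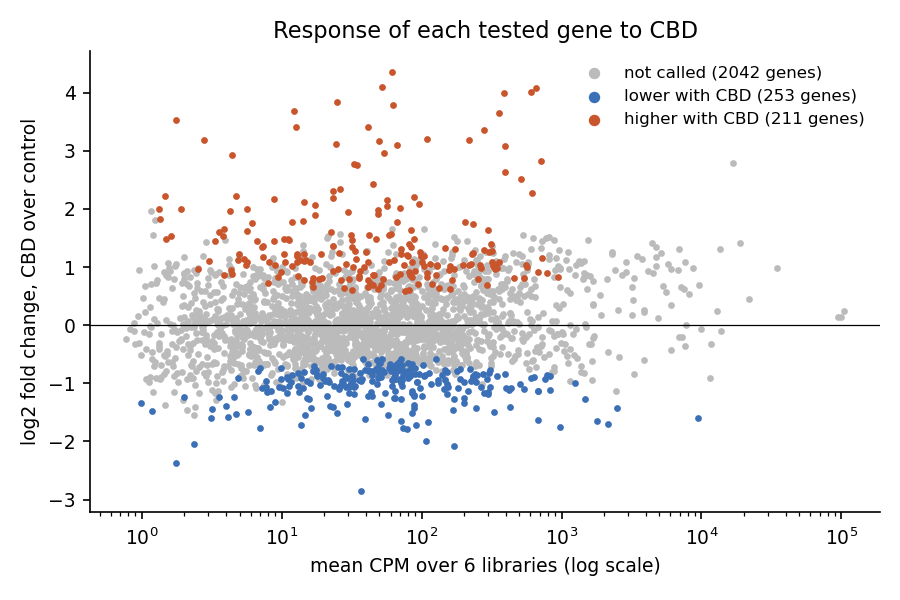
Log2 fold change of CBD over control (y axis) against the mean CPM of the 6 libraries (x axis, log scale); each point is 1 tested gene, orange where it rose, blue where it fell and grey where it was not called. The 43 rises of at least 4-fold are more numerous than the 4 falls of that size.

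Called genes were found at all levels of abundance. In 4 equal classes of mean abundance, from the lowest to the highest, 45, 52, 66 and 48 genes rose and 33, 63, 95 and 62 genes fell. Among the 20 most abundant genes, 1 fell and none rose at the adjusted threshold in edgeR's test. The 3 most abundant genes took 31.5 ± 3.72% (SD, n = 3) of the counts in controls and 28.3 ± 3.42% (SD, n = 3) with CBD, a difference smaller than the spread between replicates. The share of these 3 genes was 27.9, 31.3 and 35.3% in Controls 1, 2 and 3. It was 24.5, 29.4 and 31.0% in CBD 1, 2 and 3. The share thus rose with the replicate number in both groups, and within each number it was lower with CBD. None of these 3 genes was called. The seventh most abundant gene had a log2 fold change of 2.78 and did not pass (edgeR, adjusted p = 0.072).

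The largest rise was that of TDE_RS04325, from 5.82 ± 4.14 CPM (SD, n = 3) in controls to 116 ± 30.9 CPM (SD, n = 3) with CBD. Its log2 fold change was 4.36 with a standard error of 0.49 (edgeR, adjusted p = 0.0025). TDE_RS12480 rose from 5.98 ± 6.33 to 98.2 ± 36.8 CPM (SD, n = 3 each), a log2 fold change of 4.10 with a standard error of 0.70 (edgeR, adjusted p = 0.012). Without Control 2 the call of TDE_RS12480 was lost, with a log2 fold change of 3.74 (edgeR, adjusted p = 0.066). Without Control 1 the log2 fold change was 5.08 for TDE_RS04325 and 5.41 for TDE_RS12480. In controls TDE_RS12480 was uneven, with 13.3 CPM in Control 1 compared with 2.73 in Control 2 and 1.94 in Control 3. The largest fall was that of TDE_RS09180, from 64.7 ± 8.78 to 8.90 ± 3.49 CPM (SD, n = 3 each), a log2 fold change of -2.86 with a standard error of 0.29 (edgeR, adjusted p = 0.0025). TDE_RS04100, the next largest fall among genes with a mean of at least 20 CPM, went from 274 ± 89.3 to 65.1 ± 5.89 CPM (SD, n = 3 each), with a log2 fold change of -2.08 and a standard error of 0.27 (edgeR, adjusted p = 0.0045).

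Genes with consecutive identifiers changed together. Of 188 adjacent pairs in which both genes were called, 179 pairs, or 95.2%, went in the same direction. The 464 called genes included 154 in 35 runs of at least 3 consecutive identifiers with the same direction. Random orders of the same genes placed a median of 9 and at most 40 genes in such runs (9999 shuffles, one-sided permutation p = 1e-04, the smallest they can give). Across genes, the log2 fold changes of 2343 adjacent pairs had a Pearson correlation of 0.64, and no shuffle exceeded 0.075; genes are not independent replicates. The number of genes in such runs followed the number of calls, with 574 without Control 1, 102 without Control 3, 19 without Control 2 and 23 without either CBD 2 or CBD 3.

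**Figure D3:**
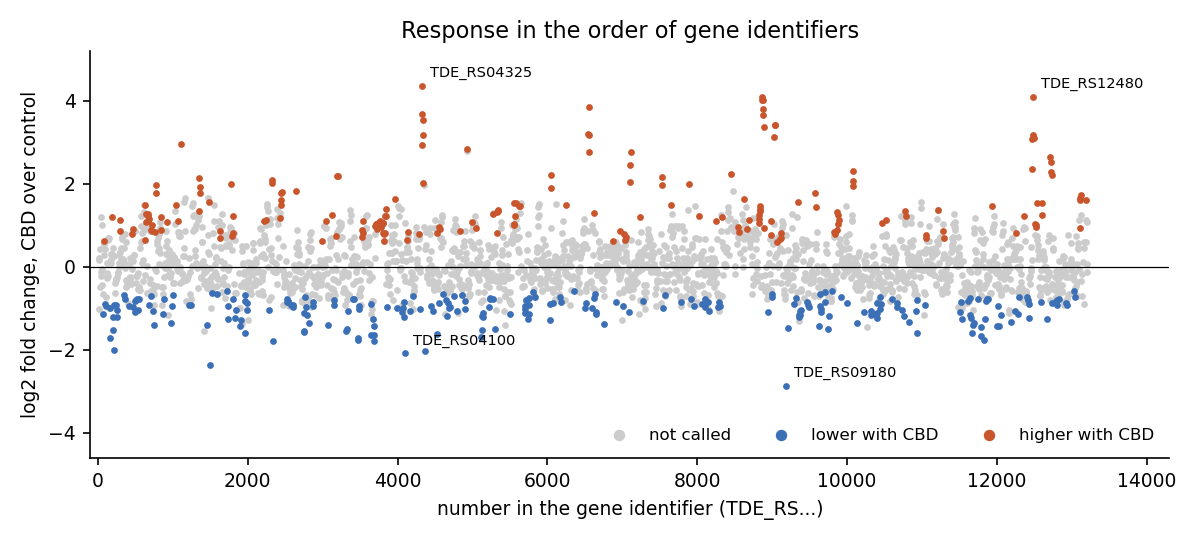
Log2 fold change of CBD over control (y axis) against the number in each gene's identifier (x axis); each point is 1 tested gene, orange where it rose, blue where it fell and grey where it was not called. The rises of TDE_RS04325 and TDE_RS12480 stand in stacks of genes with neighbouring numbers, and TDE_RS09180 is the lowest point.

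Of the 6 runs with at least 5 genes, 5 rose and 1 fell. A run of 7 genes held 6 that rose at least 4-fold, with a median of 13.8-fold over the run and a highest value of 16.9-fold; its summed level went from 318 ± 168 CPM in controls to 4440 ± 383 CPM with CBD (SD, n = 3 each). The run of 6 genes that includes TDE_RS04325 rose by 4.01- to 20.6-fold, from 10.3 ± 5.34 to 158 ± 39.6 CPM in sum (SD, n = 3 each). The run of 5 genes that includes TDE_RS12480 rose by 5.09- to 17.1-fold, from 157 ± 96.1 to 1365 ± 525 CPM in sum (SD, n = 3 each). A further run of 6 genes rose by 2.07- to 2.76-fold. The falling run had 5 genes, lower by 2.15- to 3.23-fold, and its sum went from 3956 ± 594 to 1304 ± 417 CPM (SD, n = 3 each). These runs held 14 of the 20 genes that rose at least 8-fold. The medians of these runs kept their direction in all 16 alternatives, which was hardly possible otherwise for called genes whose groups did not overlap. With the filter of 50 counts, 2 of the 6 genes in the run with TDE_RS04325 were tested. No member of the falling run, nor of the run that rose by up to 2.76-fold, was called without Control 2, without CBD 2 or without CBD 3. Their median log2 fold changes were then -1.22, -1.21 and -1.08 for the falling run, compared with -1.22 in the main test, and 1.28, 1.37 and 1.37 for the other, compared with 1.30. Of the 5 genes in the run with TDE_RS12480, 2 were called without Control 2 and 3 when any 1 of the CBD libraries was left out. The median log2 fold change of that run was then 2.89 without Control 2. It was 3.36, 3.06 and 2.85 without CBD 1, CBD 2 and CBD 3, compared with 3.10 in the main test. Without Control 1 the median log2 fold change of that run went from 3.10 to 4.53, and that of the run of 7 genes from 3.79 to 4.41.

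The longest run had 24 genes with nearly equal rises, between 1.53- and 2.13-fold with a median of 2.03-fold, although the mean abundance of its members ranged from 26.7 to 946 CPM. Its summed level was 4599 ± 191 CPM in controls and 9023 ± 1039 CPM with CBD (SD, n = 3 each). Control 1, at 4595 CPM, lay among the other controls for this run, whose members were chosen by a test that includes Control 1. No member was called without Control 2, without CBD 2, without CBD 3 or with library size as the only scaling, and the median log2 fold change in these settings was 0.98, 0.98, 0.94 and 0.66. Relative to the median of all tested genes it was 1.02 in both scalings, which follows by construction, since a scaling shifts all genes nearly alike and cannot test the rise. In that scaling the summed level of Control 3, 6641 CPM, came close to that of CBD 1, 6767 CPM.

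**Figure D4:**
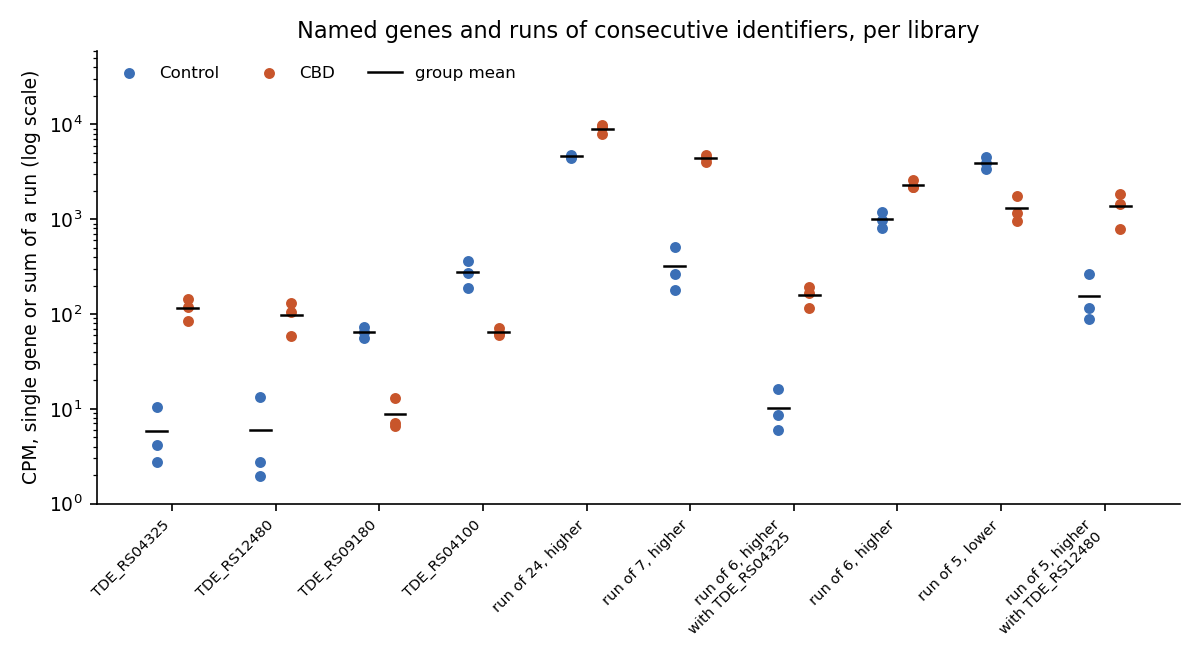
CPM of the 4 named genes and summed CPM of the 6 runs of at least 5 consecutive identifiers (y axis, log scale); each point is 1 library, blue for control and orange for CBD, and black bars are means of 3 libraries. The control and CBD points of the 24-gene run, at 4599 and 9023 CPM on average, are separate, and TDE_RS04325 shows the widest gap among the 4 single genes.

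Control 1 did not approach the CBD libraries equally for all genes. Genes were classed by the ratio of the CBD mean to the mean of Controls 2 and 3, without using Control 1, and its position was set on a linear scale where 0% is the mean of those controls and 100% the CBD mean. For 238 genes that were 2- to 4-fold higher, the median position of Control 1 was 77.1%, with a 95% bootstrap interval over genes of 70.1 to 80.5%. For 59 genes that were 4- to 8-fold higher it was 57.8%, with an interval of 51.2 to 62.6%. For 24 genes that were at least 8-fold higher it was 9.34%, with an interval of 7.37 to 21.9%. For 124 genes that were 2- to 4-fold lower it was 49.4%, with an interval of 44.9 to 53.7%. These values depended on the scale and on the baseline. For the genes at least 8-fold higher the median was 31.9% on a log2 scale and 34.9% with Control 3 alone as the baseline. With that baseline the 4- to 8-fold class stood at 80.1%, with an interval of 70.6 to 83.3%, level with the 82.4% of the 2- to 4-fold class, so the step between these classes was not kept while the class of at least 8-fold remained lower. In the test with all 6 libraries, 23 of the 24 genes in the highest class were called, compared with 58 of 238 in the 2- to 4-fold class. Control 1 enters that test, so these counts are not independent of its position. Control 2, placed between Control 3 and the CBD mean, also stood lowest for the genes at least 8-fold higher. Its median positions were 28.9% for genes 2- to 4-fold higher, 25.7% for 4- to 8-fold and 10.7% for at least 8-fold. In both comparisons the libraries that defined the classes also set 0% and 100%. A library left out can then stand further from 0% where the gap is small, so part of these gradients may come from the choice of genes.

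**Figure D5:**
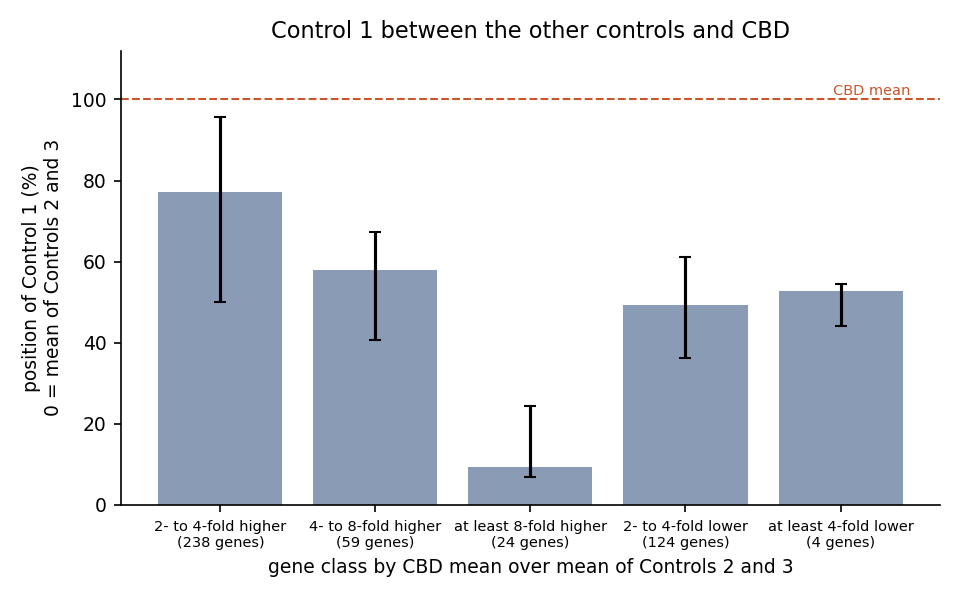
Position of Control 1 between the mean of Controls 2 and 3 (0%) and the CBD mean (100%, dashed line) on the y axis, for classes of genes by their ratio of CBD to those controls on the x axis; bars are medians over genes and error bars the quartiles. The bar of the genes at least 8-fold higher, at 9.34%, lies below that of the 2- to 4-fold class, at 77.1%; with Control 3 alone as the baseline these medians were 34.9% and 82.4%.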

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

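No called gene changed sign under any alternative, which was hardly possible for genes whose groups did not overlap and is no test of the calls. RLE and upper-quartile scaling, limma-voom, no filter, the filter of 50 counts, the library tables and the removal of the 3 most abundant genes (chosen after seeing the data) left each count within 1.5 times its main value of 211 rises, 253 falls, 148 rises of at least 2-fold and 117 falls of at least 2-fold. Upper-quartile factors nonetheless turned the balance of changes of at least 2-fold, to 131 rises and 171 falls. With library size as the only scaling the counts were 139 rises, 424 falls, 120 rises of at least 2-fold and 375 falls of at least 2-fold. The DESeq2 Wald test gave 338 rises, and its 704 calls included 463 of the 464 made by edgeR. A threshold of 0.01 left 32 rises and 13 falls, and glmTreat against 1.5-fold left 35 rises and 14 falls. Leaving out 1 library at a time gave between 32 and 574 rises, 11 and 471 falls, 32 and 432 rises of at least 2-fold, and 11 and 202 falls of at least 2-fold. The highest values came without Control 1, when all 464 calls were kept, and the lowest without Control 2, CBD 2 or CBD 3, when at most 11.4% were kept. Apart from the smaller number of libraries, the cause was not tested. With the replicate number as a block there were 415 rises, 401 falls and 238 rises of at least 2-fold. The deviations of libraries with the same number correlated at 0.40, 0.099 and 0.25, and 4 of 6 libraries correlated best with their own number. Scores on the second principal component also fell with the replicate number in both groups. These values lean towards pairing without settling it. The series' design text gives no pairing, so the main test was fitted without the block. In the 16 alternatives with a threshold of 0.05 other than glmTreat, the 4 named genes kept their direction and passed, except TDE_RS12480 without Control 2. Their log2 fold changes ranged from 4.00 to 5.08 for TDE_RS04325, 3.64 to 5.41 for TDE_RS12480, -3.25 to -2.69 for TDE_RS09180 and -2.50 to -1.82 for TDE_RS04100. All 4 passed glmTreat, and TDE_RS12480 did not pass at 0.01 (edgeR, adjusted p = 0.012). The median log2 fold change of the run with TDE_RS12480 was 3.80 with limma-voom, compared with 3.10. The position of Control 1 for genes at least 8-fold higher was 5.96% with library size alone and 31.9% on a log2 scale, and with Control 3 as the only baseline it was 34.9% compared with 82.4% for genes 2- to 4-fold higher. For genes 2- to 4-fold higher the position was 60.9% with library size alone and 86.7% on a log2 scale, compared with 77.1% in the main setting. In simulation at this depth 44.6% of 2-fold changes were recovered, with genes drawn independently and the same dispersion in both groups. Recovery in the data may differ, and a 2-fold change that was not called is not shown to be absent.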

Other observations

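The tests of Control 1 and of the splits of the libraries were chosen only after the results were seen; the shuffles and distances that bear on neighbouring genes were set out before their values were known. The likeness of neighbouring genes was found between control libraries as well. Distances were taken by identifier number. Some identifiers stand out of number order in the deposited table, such as TDE_RS13130 between TDE_RS00475 and TDE_RS00480, so not every distance need be one along the genome. Correlation of the CBD effect across genes was 0.63 at a distance of 1 identifier, 0.39 at 2, 0.24 at 3, 0.11 at 5 and 0.052 at 10. The difference between Control 1 and Control 3, which involves no CBD library, followed the same course, with 0.60, 0.32, 0.19, 0.077 and 0.014. Both controls also enter the CBD effect, and Control 1 lay towards the CBD libraries, so the comparisons are not independent. The run of 7 genes had 506 CPM in Control 1 compared with 181 CPM in Control 3, and the 24-gene run had 4595 and 4793 CPM, next to 4440 and 9023 CPM on average with CBD.

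A hypothesis for the joint movement of neighbours is that they are transcribed or regulated as local units, such as operons. It predicts a correlation that is high for adjacent identifiers and lost at a distance, and at 20 identifiers the correlation was -0.018. A dependence of the response on abundance, shared by neighbours, is argued against: shuffling genes within 10 classes of abundance gave a neighbour correlation of at most 0.083, compared with 0.64 observed. Genes that overlap and share reads may still add to the likeness of direct neighbours, and this was not tested, since strand and gene positions were not analysed here.

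Control 1 lay between the other controls and the CBD libraries. Material of CBD libraries mixed into a culture like Controls 2 and 3 would move every gene by the same share. The median positions of Control 1, 9.34% for genes at least 8-fold higher and 77.1% for genes 2- to 4-fold higher, argue against that. With Control 3 alone as the baseline they were 34.9% (interval 29.0 to 55.7%) and 82.4% (interval 74.7 to 88.9%). Control 2, placed between Control 3 and the CBD mean, stood at 10.7% and 28.9%, so controls also differed by class among themselves. Mixing into a culture that already differed from the other controls is not tested by these positions. Whether Control 1 was a CBD culture under a wrong label is not settled by the genes at least 8-fold higher. Its median position for these genes was below that of each CBD library. There the median of Control 1 was 9.34% with an upper bound of 21.9%, and the lowest CBD library stood at 78.5%. Bound and lowest library were 59.6% and 92.6% on a log2 scale, and 55.7% and 96.0% with Control 3 as the baseline. These bounds treat genes as independent, while 14 of the 20 genes called at least 8-fold higher stood in runs. The bounds are therefore likely too narrow. The CBD libraries also helped to choose these genes, and their mean set the upper end of the scale. Control 1 was left out of both steps. A CBD culture left out in the same way could also stand lower, and no CBD library was placed so. Scaling is argued against by rank correlations, which no scaling changes: that of Control 1 with the CBD libraries was on average 0.026 higher than with Control 3, although with Control 2, at 0.979, it was higher than with any CBD library. By the chi-square between counts, Control 1 was nearer to CBD 1, at 151 per degree of freedom, than to Control 2, at 218. CBD 2 and CBD 3, at 222 and 307, were farther from it than Control 2. A difference in the state of the cultures at harvest also stays open and was not tested.

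Among the 10 splits of the 6 libraries into groups of 3, the real one, 1 of 10, gave 464 genes and the highest other gave 0; 10 splits are too few for a share under 0.05.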
